A study of Mus musculus with 8 samples.

How the data were processed

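Single-nucleus RNA was measured in 8 spinal cord libraries of female C57BL/6JN mice with a droplet 3' gene expression kit (10x Genomics). The thoracolumbar cord was used, and per the labels nuclei were stained for Olig2, a marker of the oligodendrocyte lineage, and NeuN, a marker of neurons, and passed through a sorter. Which fraction was collected is not given in the sources used here, so shares of nuclei can depend on the gate. The labels give 4 groups: control (n = 1), experimental autoimmune encephalomyelitis (EAE, an induced inflammatory demyelinating disease; n = 2), EAE with a bone marrow transplant (EAE+BMT; n = 2), and EAE with a bone marrow transplant and PLX, an inhibitor of the CSF1 receptor on which microglia depend (EAE+BMT+PLX; n = 3). The labels do not say whether replicates are separate animals, so p-values measure the spread between samples. The conditioning before the transplant is not given in the sources used here.

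The authors deposited, for each library, a matrix of raw UMI counts per gene and barcode, made according to the submitters' processing notes with Cell Ranger 4.0.0 on the mm10 mouse genome. The headers of the 8 matrix files name version 6.1.2, so which version made the counts is uncertain. Each matrix held 32286 features, the last of which was a GFP sequence that the comparisons of the report do not use. Gene positions are those of build GRCm38/mm10 in GENCODE release M21; 19130 of 19153 tested gene identifiers were found there. The libraries held 7814 to 10215 barcodes and 40713845 to 69724333 UMIs.

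Doublets were called per library with Scrublet in scanpy 1.11.5 (expected rate 6%, 30 principal components). In EAE+BMT+PLX replicate 1 the automatic threshold called 0.0245% of barcodes, and the median threshold of the other libraries was used there, a choice made after the data were seen. Between 2.87% and 3.98% of barcodes per library were removed as doublets. Nuclei with under 500 detected genes or over 5% mitochondrial counts were left out (278 barcodes), and 69927 of 72649 barcodes were kept. Counts were scaled per nucleus and log transformed, and 2000 variable genes, 30 principal components, 20 neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9) gave 35 clusters.

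Each cluster was named from fixed marker lists of 13 candidate classes, among them granulocytes, which named no cluster. A marker counted where it was detected in at least 10% of a cluster's nuclei and reached 20 CPM in some cluster. A name needed at least 3 such markers, a score 1.5 times the second and 20 nuclei. Candidate types whose markers were detected in no cluster were dropped, a rule set after the clusters were seen. Names carry the ending -like, since they rest on RNA alone. Myeloid-like nuclei were clustered again (1000 variable genes, 20 components, resolution 0.6) without the 41 marker genes that enter the naming, and their clusters were named microglia-like or macrophage-like from 10 and 12 markers. A cluster with more markers of another class than of its own among its 10 leading genes stayed unnamed; this requirement was applied after the values had been seen and moved 1 cluster of 710 nuclei, led by Gabrb1, Gpc6 and Ntm, from microglia-like to unnamed. That cluster held 13.7% of myeloid-like nuclei in EAE, 8.74% in EAE+BMT, 1.56% in EAE+BMT+PLX and 0 in the control.

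Counts were summed per library and class for classes with at least 20 nuclei in a library and tested in edgeR 4.0.16 (R 4.3.3, limma 3.58.1) with the quasi-likelihood F test. The fit held all 8 libraries in 4 groups, TMM scaling, filterByExpr (minimum count 10, minimum total 15), robust dispersions and Benjamini-Hochberg adjustment at 0.05 within each class and contrast. The single control was assumed to vary like the other groups; its side of a difference has no replicate. The residual degrees of freedom were 4. Errors of log2 fold changes are standard errors derived from the fold change and its F statistic; errors of CPM and shares are SD between libraries. Numbers of nuclei per class were tested the same way without TMM. Shares of single libraries carry exact Clopper-Pearson 95% intervals, and a count of 0 allows 3 counts; both cover counting error only. Folds against a control with 0 counts are lower bounds on its library's 3 counts, and folds against 1 to 3 control counts carry a counting interval.

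Fixed gene lists were tested with camera (preset correlation 0.01, and again with an estimated correlation), adjusted over the lists of 1 class and contrast. In myeloid-like nuclei these were homeostatic microglia, bone marrow-derived macrophage, disease-associated and phagocytic, MHC class II presentation, MHC class I presentation, interferon response, inflammatory cytokines and chemokines, cholesterol and lipid handling, and complement and Fc receptors. In astrocyte-like nuclei they were reactive and homeostatic astrocyte genes, and in oligodendrocyte-like nuclei disease-associated, myelin, and differentiation genes. Cholesterol biosynthesis, p53 targets, immediate early, proliferation, mitochondrially encoded and Y-linked genes were tested in every class. List members were also adjusted over the list alone.

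The share of myeloid-like nuclei with a UMI of a gene was taken after thinning each nucleus to 2900 UMIs, the 25th percentile of myeloid-like nuclei (seed 7), beside the same share in oligodendrocyte-like nuclei as background. Relations with the clinical score of the labels used Pearson's r and Spearman's rho over the 7 EAE libraries with exact two-sided permutation tests. The file names carry 3 prefixes of unknown meaning (D1, D2 and D3), and differences were recomputed within D2 and D3. Prefix D2 held the control and 1 library of each EAE group, D3 held 1 library of each EAE group, and D1 held 1 library. With the prefix as a factor, that library (EAE+BMT+PLX replicate 1) has its own coefficient and does not inform the differences between groups.

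Named genes were, per class and contrast, the up to 8 with the largest log2 fold change in each direction among genes with adjusted p under 0.05, a mean of at least 20 CPM, a named symbol and no overlap of the libraries of the groups. Where under 3 passed, the 3 smallest p-values were added, given as not passing, and up to 4 members of each list and 8 fixed genes were named whatever their p. Some genes that the rule chose are not reported here. The groups, tests, lists, named-gene rule and most alternatives were chosen before the data were examined. The alternatives were RLE scaling, DESeq2 1.42.0, no low-count filter, doublets kept, 1000 detected genes, every barcode, 50 nuclei per library, doubled resolution (49 clusters), prefix or replicate number as a factor, fits of the compared groups alone, a denominator without oligodendrocyte-like and neuron-like nuclei, unthinned shares, and each library left out. After the data were seen, 4 alternatives were added: clustering of myeloid-like nuclei with the marker genes, separate fits of microglia-like and macrophage-like nuclei, myeloid-like nuclei without a cluster that carried oligodendrocyte RNA, and fits without both EAE+BMT replicate 1 and EAE+BMT+PLX replicate 1.

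The test was checked on simulated data with fold changes of 4 planted in 95 to 100 genes per contrast. It recovered 51.5% of them in myeloid-like, 70.0% in astrocyte-like and 61.2% in oligodendrocyte-like nuclei for EAE against control, and 73.7% to 89.8% in the other contrasts; of fold changes of 2 it recovered 5.10% to 49.5%. False calls made up 5.08% to 15.1% of its calls. Other software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, anndata 0.12.19 and matplotlib 3.10.9.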

Results

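The data were single-nucleus counts from 8 thoracolumbar spinal cord libraries: 1 control, 2 EAE, 2 EAE+BMT and 3 EAE+BMT+PLX. The control library held 46167521 UMIs in 9763 barcodes. The EAE replicates held 40713845 and 62377344 UMIs, the EAE+BMT replicates 47521522 and 69724333, and the EAE+BMT+PLX replicates 50710712, 51251660 and 60699240. Median UMIs per barcode ranged from 3909 in the control to 5976 in EAE replicate 2. The clinical scores of the labels were 0 for the control, 3.5 and 3 for EAE, 3.5 and 1.25 for EAE+BMT, and 2, 1.25 and 2.75 for EAE+BMT+PLX. Of the 69927 kept nuclei all but 1 fell into 12 named classes, led by oligodendrocyte-like (43099), myeloid-like (9419), astrocyte-like (8024), neuron-like (3030), oligodendrocyte precursor-like (OPC-like; 2969) and T cell-like nuclei (861). The remaining classes were fibroblast-like (839), ependymal-like (565), endothelial-like (545), mural-like (233), B cell-like (206) and Schwann cell-like nuclei (136). Genes are named with their CPM or log2 fold change summed per library and class, and positions are on GRCm38/mm10.

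In EAE against control, the question was which cell classes differed in the diseased cord. T cell-like nuclei made up 1.96% ± 0.10 of nuclei in EAE (SD, n = 2) and 0.0107% in the control (1 of 9373; exact 95% interval 0.00027% to 0.0594%). Myeloid-like nuclei, the class of microglia and macrophages, made up 20.9% ± 2.08 in EAE and 6.82% in the control (interval 6.32% to 7.35%). B cell-like nuclei stood at 0.33% and 0.0107%, oligodendrocyte-like nuclei at 54.4% ± 4.89 and 64.7%, and astrocyte-like nuclei at 11.6% ± 4.59 and 19.0%. T cell-like nuclei rose by 7.34 on the log2 scale (SE 0.88; edgeR adjusted p = 0.0023; 7.47 within prefix D2). With the replicate number as a block the value was 7.32, and that call did not pass (adjusted p = 0.070). The difference was 1.62 (SE 0.48) for myeloid-like nuclei (adjusted p = 0.083; 1.51 within D2), 4.80 (SE 1.53) for B cell-like nuclei (adjusted p = 0.083) and -0.25 (SE 0.30) for oligodendrocyte-like nuclei (adjusted p = 0.53). All shares hold for nuclei sorted on Olig2 and NeuN, with the collected fraction not given.

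The transplant and PLX comparisons asked how the classes differed with the bone marrow transplant, alone or with PLX. Myeloid-like nuclei made up 12.6% ± 4.24 in EAE+BMT (n = 2) and 12.1% ± 2.65 in EAE+BMT+PLX (n = 3). T cell-like nuclei made up 1.33% ± 0.54 and 1.16% ± 0.34, oligodendrocyte-like nuclei 61.1% ± 5.48 and 64.7% ± 5.74, and astrocyte-like nuclei 11.7% ± 2.10 and 8.52% ± 1.74. OPC-like nuclei stood at 5.09% in the control, 4.11% in EAE, 3.82% in EAE+BMT and 4.28% in EAE+BMT+PLX, and neuron-like nuclei at 1.58%, 3.56%, 3.26% and 6.94%, the last from replicates at 14.1%, 3.30% and 3.39%. Against EAE the log2 difference in myeloid-like nuclei was -0.73 (SE 0.36; adjusted p = 0.55) for EAE+BMT and -0.79 (SE 0.32; adjusted p = 0.59) for EAE+BMT+PLX. Within prefixes D2 and D3 it was -0.32 and -1.22 for EAE+BMT, and -0.97 and -0.98 for EAE+BMT+PLX. T cell-like nuclei differed by -0.56 (SE 0.43; adjusted p = 0.68; -0.14 and -1.09 within D2 and D3) and -0.76 (SE 0.39; adjusted p = 0.59; -0.38 and -0.72). Between EAE+BMT+PLX and EAE+BMT the differences were -0.06 (SE 0.33; adjusted p = 0.86) for myeloid-like and -0.20 (SE 0.39; adjusted p = 0.75) for T cell-like nuclei, and within D2 and D3 they were -0.65 and 0.23, and -0.23 and 0.37. No class passed the test in these 3 contrasts.

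**Figure D1:**
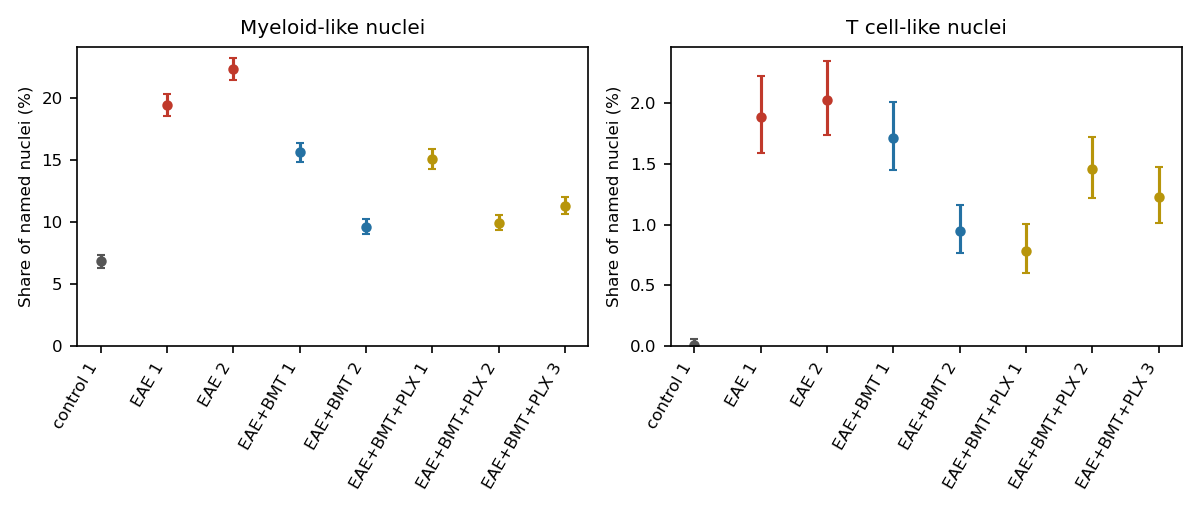
Share of nuclei (%) that were myeloid-like and T cell-like in each of the 8 libraries, with exact 95% intervals. Myeloid-like nuclei made up 6.82% in the control and 19.4% and 22.4% in the EAE libraries.

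Within the myeloid-like class, macrophage-like nuclei made up 0.94% in the control (6 of 639; exact 95% interval 0.35% to 2.03%), 5.40% ± 1.02 in EAE, 22.7% ± 3.24 in EAE+BMT and 62.3% ± 25.2 in EAE+BMT+PLX. The EAE+BMT+PLX replicates stood at 91.3%, 45.6% and 50.1%. With the marker genes in the clustering, an alternative chosen after the data were seen, the shares were 0.94%, 3.23% ± 1.65, 15.1% ± 5.20 and 36.5% ± 16.2, with 55.2%, 26.6% and 27.7% in the EAE+BMT+PLX replicates. A cluster of 663 nuclei named macrophage-like had scores of 0.56 and 0.36 (0.564 and 0.355 before rounding), close to the margin of 1.5 times. Microglia-like nuclei made up 98.1% in the control, 37.8% ± 7.54 in EAE, 32.9% ± 4.28 in EAE+BMT and 16.5% ± 13.6 in EAE+BMT+PLX. Unnamed nuclei made up the remaining 0.94%, 56.8% ± 8.55, 44.5% ± 1.04 and 21.1% ± 12.2. Of the control's 639 myeloid-like nuclei, 613 lay in 1 cluster of 638 led by Khdrbs3, Dlc1 and Rtn1, nearly the control library alone. Macrophage-like nuclei rose by 2.51 on the log2 scale (SE 0.93; adjusted p = 0.039) in EAE against control, by 2.07 (SE 0.64; adjusted p = 0.036) in EAE+BMT against EAE, and by 3.53 (SE 0.66; adjusted p = 0.0019) in EAE+BMT+PLX against EAE. Within prefix D2 these were 2.32, 2.41 and 3.28, and within D3 the last pair was 1.74 and 3.03. In EAE+BMT+PLX against EAE+BMT the difference was 1.46 (SE 0.59; adjusted p = 0.11), or 0.87 and 1.30 within D2 and D3. Microglia-like nuclei differed by -1.38 (SE 1.25; adjusted p = 0.30), -0.20 (SE 1.06; adjusted p = 0.85), -1.19 (SE 0.95; adjusted p = 0.25) and -0.99 (SE 0.95; adjusted p = 0.33) in the 4 contrasts, and by -1.60 in EAE against control within D2. Unnamed nuclei rose by 5.90 (SE 1.30; adjusted p = 0.0052) in EAE against control.

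These calls rested on few libraries. With the replicate number as a block none of the 3 macrophage-like rises passed (adjusted p = 0.16, 0.32 and 0.060). The macrophage-like rise in EAE against control did not pass without EAE replicate 1 or 2 (adjusted p = 0.096 and 0.15), EAE+BMT replicate 1 or 2 (both 0.10), or EAE+BMT+PLX replicate 2 or 3 (0.061 and 0.074), nor with the marker genes in the clustering (1.77, adjusted p = 0.13). The rise in EAE+BMT against EAE did not pass without EAE replicate 1 or 2 (adjusted p = 0.34 and 0.21), EAE+BMT replicate 1 or 2 (0.24 and 0.15), or EAE+BMT+PLX replicate 2 or 3 (0.062 and 0.080). The rise in EAE+BMT+PLX against EAE had an adjusted p of 0.053 without EAE replicate 1. Without EAE+BMT+PLX replicate 1, the difference in macrophage-like nuclei between EAE+BMT+PLX and EAE+BMT was 1.07 (adjusted p = 0.0019). The microglia-like difference was then -1.37 (adjusted p = 0.00042) in EAE against control and -0.66 (adjusted p = 0.012) in EAE+BMT+PLX against EAE. With the prefix as a factor the same 3 differences were 1.07 (adjusted p = 0.016), -1.42 (adjusted p = 0.0056) and -0.64 (adjusted p = 0.043).

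**Figure D2:**
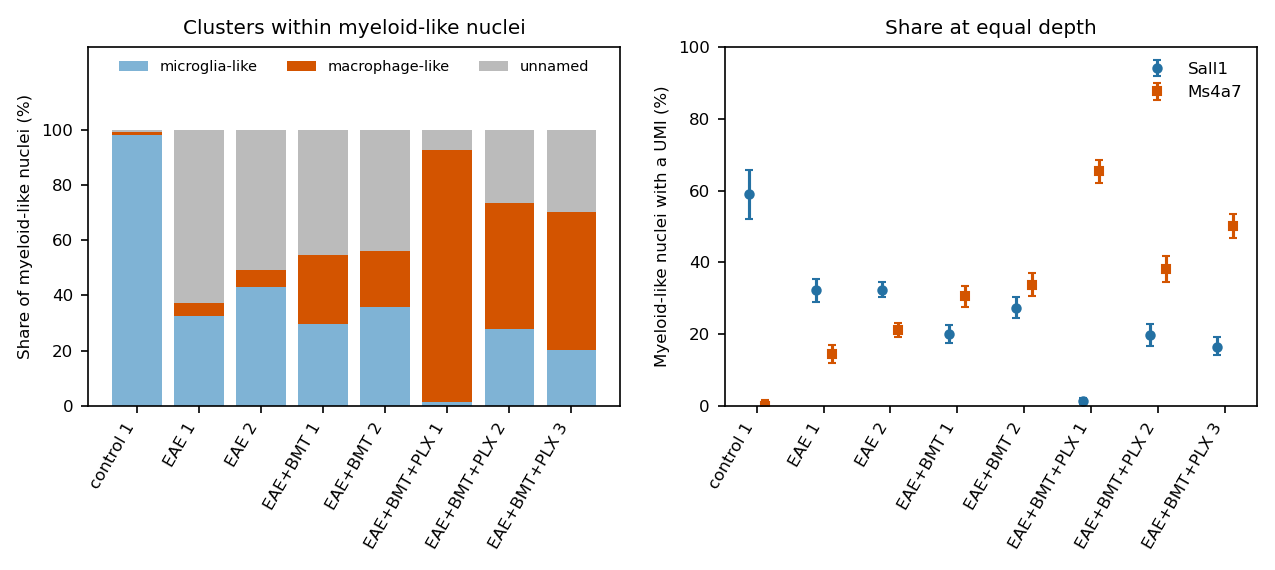
Left, microglia-like, macrophage-like and unnamed nuclei as % of myeloid-like nuclei in each library; right, share (%) of myeloid-like nuclei with a UMI of Sall1 and Ms4a7 at 2900 UMIs, with exact 95% intervals. Macrophage-like nuclei made up 0.94% in the control and 45.6% to 91.3% in the EAE+BMT+PLX libraries.

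At an equal depth of 2900 UMIs, Sall1 (chromosome 8, 89027235 to 89044162, minus strand), which encodes a transcription factor of microglia, had a UMI in 59.0% of myeloid-like nuclei in the control, 32.3% ± 0.17 in EAE, 23.6% ± 5.25 in EAE+BMT and 12.5% ± 9.83 in EAE+BMT+PLX. The background in oligodendrocyte-like nuclei was 7.40%, 7.42%, 7.78% and 8.65%. Ms4a7 (chromosome 19, 11321039 to 11336146, minus strand), a membrane protein gene of macrophages, had a UMI in none of 212 control nuclei and in 17.7% ± 4.75, 32.1% ± 2.24 and 51.2% ± 13.7 of the EAE, EAE+BMT and EAE+BMT+PLX nuclei, over a background of at most 0.65%. P2ry12, a purinergic receptor of resting microglia, was seen in 90.6%, 60.9%, 55.0% and 50.7%, with a background of 1.01% to 1.93%. Cx3cr1, the fractalkine receptor, was seen in 91.5%, 67.5%, 57.6% and 55.7%, and Tmem119, another microglial gene, in 30.2%, 14.3%, 12.5% and 13.3%, over backgrounds of 2.54% to 3.74% and at most 0.40%. Gpnmb, a lysosomal glycoprotein gene of phagocytes, was seen in 0%, 37.6%, 48.8% and 56.5%, Clec12a in 0%, 3.27%, 9.68% and 20.8%, and F13a1 in 0%, 2.80%, 9.29% and 8.90%, over backgrounds of at most 3.92%, 0.25% and 0.26%. Spp1, which encodes osteopontin, stood at 0.94%, 14.6%, 10.1% and 17.4%, over a background of 0.40%, 2.82%, 1.45% and 1.98%. The MHC class II genes Cd74 and H2-Ab1 stood at 0.47%, 20.9%, 26.9% and 16.1%, and at 0%, 6.79%, 11.5% and 9.52%, over backgrounds of at most 2.99% and 1.11%. Apoe, an apolipoprotein gene, was seen in 17.0%, 89.9%, 88.3% and 90.6%, but its background was 29.6%, 60.6%, 57.0% and 57.7%, so the control share lay under it. Of the control's myeloid-like nuclei 427 were too shallow to enter, and no test was run between groups.

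In myeloid-like nuclei of EAE against control, 522 genes rose and 273 fell of 14919 tested. The largest rises were in genes that were near 0 in the control. Gpnmb (ENSMUSG00000029816; chromosome 6, 49036546 to 49070929, plus strand) reached 910 CPM ± 309 and was at least 493-fold higher. Hpse, which encodes heparanase, was at least 62.2-fold and Igf2r, the mannose-6-phosphate receptor of lysosomal sorting, at least 25.6-fold higher. Atp6v0d2, a subunit of the vacuolar proton pump, was 476 times higher (counting interval 85.3 to 18794), Xdh, xanthine dehydrogenase, 192 times (65.8 to 933), Ms4a7 187 times (33.6 to 7400) and Lgals3, galectin 3, 115 times (39.5 to 560). Colec12, a scavenger receptor gene, rose by 6.69 (SE 0.70; adjusted p = 0.0059). Among genes that fell, Khdrbs3, an RNA-binding protein gene, changed by -4.68 (SE 0.32; adjusted p = 0.00074), Bank1 by -3.80, Bnc2 by -3.10, Nhs by -2.94, Dlc1 by -2.80, Asb2 by -2.71, Rtn1 by -2.66 and Cmya5 by -2.55. Bank1 and Bnc2 also stand on the marker lists of B cells and fibroblasts. The named genes past the threshold moved the same way within prefix D2 (34 of 34). The count of 795 fell to 402 without EAE replicate 1, 362 without EAE replicate 2 and 411 without EAE+BMT+PLX replicate 3, was 1342 with the prefix as a factor, and was 1824 without EAE+BMT replicate 1 and EAE+BMT+PLX replicate 1. DESeq2 called 1091.

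Of 19 measured disease-associated and phagocytic genes, 15 rose and 0 fell in EAE (17 and 0 adjusted over the list alone), with a median log2 fold change of 3.35, or 3.08 with genes near 0 at their bound. Apoe (ENSMUSG00000002985; chromosome 7, 19696109 to 19699188, minus strand) rose from 153 to 1553 CPM ± 42.1, by 3.35 (SE 0.31; adjusted p = 0.0016). Axl, a receptor kinase for apoptotic cells, rose by 4.48 (SE 0.31), Igf1 by 4.46 (SE 0.58), Spp1 by 5.99 (SE 1.23), Lpl, lipoprotein lipase, by 3.85 (SE 0.72), and the cathepsin genes Ctsb and Ctsd by 1.78 (SE 0.25) and 1.54 (SE 0.31). Of 16 bone marrow-derived macrophage genes, 6 rose and 0 fell (10 and 0 adjusted over the list alone), among them Itga4, an integrin of leukocyte entry, by 3.28 (SE 0.41), and Lyz2, lysozyme, by 3.18 (SE 0.66); the median was 3.13, or 2.38 with bounds. Of 16 cholesterol and lipid handling genes, 5 rose and 0 fell (8 and 1 adjusted over the list alone), among them the cholesterol exporters Abcg1 by 3.26 (SE 0.40) and Abca1 by 2.31 (SE 0.33), Soat1, which esterifies cholesterol, by 1.51 (SE 0.29), and Lipa, the lysosomal lipase, by 1.61 (SE 0.37); the median was 1.07. Of 16 homeostatic microglia genes, 0 rose and 1 fell by edgeR (0 and 1 adjusted over the list alone), with a median of -1.03. P2ry12 (ENSMUSG00000036353; chromosome 3, 59216272 to 59262871, minus strand) fell from 1129 to 546 CPM ± 55.1, with a log2 fold change of -1.05 (SE 0.24; adjusted p = 0.041). The values of Sall1, Csf1r, Cx3cr1 and Tmem119 were -0.94 (SE 1.11), -0.37 (SE 0.21), -0.81 (SE 0.26) and -1.25 (SE 0.39), none past the threshold.

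These lists passed camera with adjusted p = 6.1e-29 for disease-associated and phagocytic, 1.4e-13 for bone marrow-derived macrophage, 1.9e-07 for cholesterol and lipid handling, and 4.6e-07 for homeostatic microglia genes. None passed with an estimated correlation (adjusted p = 0.089, 0.094, 0.20 and 0.47). MHC class I presentation had a median of 0.98 (adjusted p = 0.00042, and adjusted p = 0.74 with an estimated correlation) with no member past the threshold, Nlrc5, an activator of MHC class I genes, at 2.98 (SE 0.71; adjusted p = 0.066). The mitochondrially encoded genes, a sign of RNA quality, moved with these lists: 0 rose and 1 fell of 8 (0 and 6 adjusted over the list alone), with mt-Co2 at -1.67 (SE 0.39), a median of -1.43, and adjusted p = 1.4e-05, or adjusted p = 0.47 with an estimated correlation. Median mitochondrial counts per barcode were 0.0374% in the control, 0.0141% and 0.0129% in EAE. Lists that did not pass were MHC class II presentation (median 0.21; Cd80, a costimulator, fell by 0.89, and H2-Aa stood at 4.37 with SE 1.86), interferon response (0.59), inflammatory cytokines and chemokines (1.61, or 0.38 with bounds; Cxcl16 rose by 1.61), p53 targets (0.11), proliferation (0.50, or -0.13 with bounds), complement and Fc receptors (-0.12), cholesterol biosynthesis (-0.04) and immediate early genes (1.19, or -0.56 with bounds; Klf2 changed by -3.19). Within MHC class II, H2-Ab1 and H2-Eb1 were 23.8 and 30.2 times higher (counting intervals 6.56 to 197 and 8.33 to 250), unlike the median. H2-Oa stood at 0.78 times (0.18 to 7.03). Complement and Fc receptors (Fcgr2b 1.16, C3ar1 1.24) had a mean of 0.95 and a test direction up, against the negative median. Cholesterol biosynthesis had a mean of 0.13 and a test direction down, and for immediate early genes the test direction was down, against a mean of 0.70. Mean log2 CPM within prefix D2 differed by 2.88 for disease-associated and phagocytic, 2.37 for bone marrow-derived macrophage, 1.30 for cholesterol and lipid handling, -1.26 for homeostatic microglia, 1.39 for MHC class I and -1.21 for mitochondrially encoded genes. Y-linked genes were under the filter in myeloid-like nuclei.

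**Figure D3:**
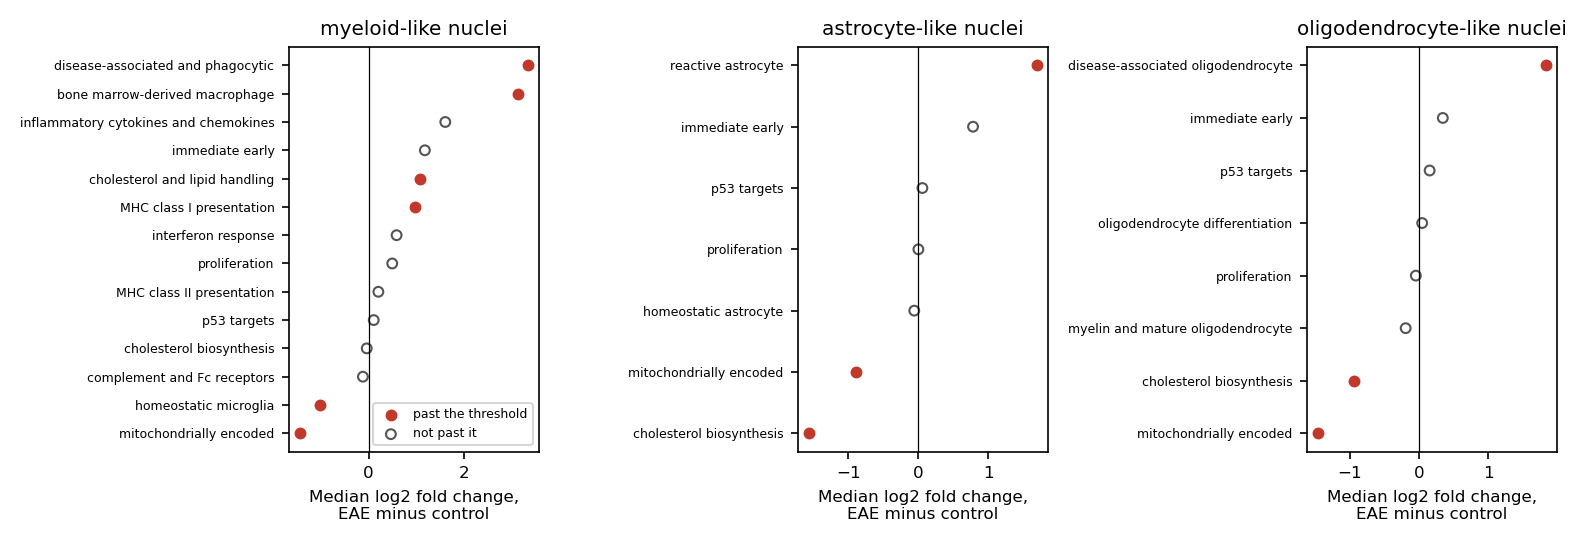
Median fitted log2 fold change of each gene list in EAE against control in myeloid-, astrocyte- and oligodendrocyte-like nuclei; filled points passed camera with the preset correlation, and none passed with an estimated one. Disease-associated and phagocytic genes stood at 3.35 in myeloid-like nuclei and cholesterol biosynthesis at -1.56 in astrocyte-like nuclei.

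In myeloid-like nuclei of EAE+BMT against EAE, the question was what differed with the transplant in the diseased cord. The smallest p-values under the naming rule belonged to Ifi203 (2.24, SE 0.36), Mndal (1.96, SE 0.33), both interferon-inducible nuclear sensor genes, and Sirpb1b (1.76, SE 0.30), a signal-regulatory receptor gene, and to Hhat (-1.16, SE 0.22), Efr3b (-0.84, SE 0.20) and Tbc1d16 (-0.63, SE 0.16), each with an adjusted p of 1. The class lay in different clusters in the groups: 1 cluster held 5.89% of its nuclei in EAE, 24.6% in EAE+BMT and 67.1% in EAE+BMT+PLX. In macrophage-like nuclei taken alone, a fit chosen after the data were seen, Ifi203, Mndal and Sirpb1b stood at 0.46 (SE 0.22), 0.26 (SE 0.18) and 0.25 (SE 0.34). In microglia-like nuclei they stood at 1.76 (SE 0.99), 1.55 (SE 0.73) and 2.26 (SE 1.14), none past the threshold. Of the bone marrow-derived macrophage genes 0 passed over all genes and 5 rose adjusted over the list alone: Klra2 (2.06, SE 0.37), Mrc1, the mannose receptor (1.87, SE 0.43), Itga4 (0.72, SE 0.23), Clec12a (1.53, SE 0.42) and F13a1 (2.17, SE 0.59). That list had a median of 0.87 (camera adjusted p = 3.1e-22, and adjusted p = 0.065 with an estimated correlation; 1.47 and 0.35 within D2 and D3). Interferon response genes were higher in 19 of 19, with Irf7 at 1.14 (SE 0.46), and a median of 0.80 (adjusted p = 4.0e-09, and adjusted p = 0.70 with an estimated correlation), but the difference was 1.31 within D2 and -0.25 within D3, and the median was -0.04 without EAE+BMT replicate 1. Inflammatory cytokines and chemokines had a median of 0.36 (adjusted p = 0.032, and adjusted p = 0.70 with an estimated correlation; Tnf 1.25, SE 0.37) with 1.15 within D2, -0.41 within D3 and -0.14 without EAE+BMT replicate 1. Homeostatic microglia genes had a median of -0.21 (adjusted p = 0.0050, and adjusted p = 0.70 with an estimated correlation), with P2ry12 at -0.20, Sall1 at -0.53 (SE 0.92) and Csf1r at -0.26 (SE 0.17), -0.60 within D2, 0.04 within D3, and a median of -0.05 with an upward test direction without EAE+BMT replicate 1. The p53 targets had a median of 0.28 with 12 of 13 higher (adjusted p = 0.00050, and adjusted p = 0.52 with an estimated correlation; 0.44 and 0.19 within D2 and D3).

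By edgeR 0 of 14919 genes passed in this contrast, 380 had an unadjusted p under 0.05, and DESeq2 called 12. Without EAE+BMT replicate 2, edgeR called 3 genes, and without the low-count filter 7. The medians of the lists that did not pass were -0.07 for disease-associated and phagocytic genes (Apoe -0.01, SE 0.21), 0.16 for MHC class II, 0.37 for MHC class I, 0.18 for cholesterol and lipid handling, -0.01 for complement and Fc receptors, 0.15 for cholesterol biosynthesis, 0.15 for immediate early, -0.25 for proliferation and 0.07 for mitochondrially encoded genes. The MHC class I median was -0.51 without EAE+BMT replicate 1.

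In myeloid-like nuclei of EAE+BMT+PLX against EAE, 13 genes rose and 2 fell. Ifi203 (ENSMUSG00000039997; chromosome 1, 173920407 to 173942672, minus strand) rose from 13.4 ± 4.33 to 101 CPM ± 26.4, by 2.89 (SE 0.34; adjusted p = 0.039). Nlrc4 (ENSMUSG00000039193; chromosome 17, 74425438 to 74459142, minus strand), an inflammasome sensor gene, rose by 2.87 (SE 0.30; adjusted p = 0.032), from 5.82 ± 0.82 to 42.2 CPM ± 11.8. Mndal rose by 2.77 (SE 0.32), Sirpb1b by 2.25 (SE 0.28), Ms4a14 by 1.86 (SE 0.24), Per2, a circadian clock gene, by 1.30 (SE 0.18), and Psd3 by 1.01 (SE 0.13). Npl, which encodes a sialic acid lyase, and Anapc15, a subunit of the anaphase-promoting complex, changed by -1.30 (SE 0.18) and -1.02 (SE 0.14). Mndal (chromosome 1, 173849126 to 173942491) and Ifi203 overlap on 1 strand, which leaves the split of reads between them uncertain. The named genes moved the same way within both prefixes (9 of 9). That was fixed in advance, since the naming rule asked that the libraries of the groups not overlap. In macrophage-like nuclei taken alone, a fit chosen after the data were seen, Ifi203 stood at -0.12 (SE 0.20), Mndal at -0.13 (SE 0.17), Nlrc4 at -0.03 (SE 0.24), Sirpb1b at -0.39 (SE 0.31), Ms4a14 at 0.66 (SE 0.31), Psd3 at 0.28 and Per2 at 0.97 (SE 0.42). Those nuclei lay in 3 clusters, with 113, 52 and 20 nuclei in EAE and 277, 1147 and 599 in EAE+BMT+PLX. Mndal and Ifi203 were among the leading genes of the last. In microglia-like nuclei taken alone Ifi203 stood at 2.12 (SE 1.02), Mndal at 1.55 (SE 0.78), Sirpb1b at 2.47 (SE 1.21), Ms4a14 at -0.79 (SE 1.65), Psd3 at 0.13 (SE 0.21) and Per2 at 1.46 (SE 0.41), none past the threshold. The count of 15 was 0 by edgeR without EAE replicate 1 or 2 or without EAE+BMT+PLX replicate 2 or 3, 50 without EAE+BMT+PLX replicate 1, 28 and 23 without EAE+BMT replicate 1 and 2, and 147 without EAE+BMT replicate 1 and EAE+BMT+PLX replicate 1. It was 71 with the prefix as a factor and 211 by DESeq2, and 1329 genes had an unadjusted p under 0.05.

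Among the lists, 0 bone marrow-derived macrophage genes passed over all genes by edgeR and 11 rose adjusted over the list alone, with a median of 1.22 (camera adjusted p = 1.4e-20, and adjusted p = 0.077 with an estimated correlation; 1.63 and 0.56 within D2 and D3). Its members Clec12a, Klra2, Ms4a7 and Lyz2 stood at 2.65 (SE 0.40), 2.62 (SE 0.36), 1.82 (SE 0.36) and 1.71 (SE 0.37). Homeostatic microglia genes had a median of -0.36 (adjusted p = 0.021, and adjusted p = 0.93 with an estimated correlation; 0.13 and -0.29 within D2 and D3), with Sall1 at -1.41 (SE 0.84), P2ry12 at -0.27 (SE 0.18) and Csf1r, the receptor that PLX inhibits, at -0.36 (SE 0.16; adjusted p = 0.56). Disease-associated and phagocytic genes stood at 0.28 (0.58 and -0.21 within D2 and D3; Apoe 0.31, SE 0.19), cholesterol and lipid handling at 0.25 (0.31 and 0.07; Pparg 1.47, SE 0.35), p53 targets at 0.24 (0.50 and 0.09) and proliferation at 0.51 (0.85 and -0.17; Top2a 1.44, SE 0.51), each with adjusted p = 0.027. With an estimated correlation these 4 lists had adjusted p = 0.92. The medians of the others were 0.25 for MHC class II, 0.00 for MHC class I, 0.11 for interferon response (Bst2 1.56, SE 0.27), 0.01 for inflammatory cytokines and chemokines (0.32 with bounds), -0.09 for complement and Fc receptors, 0.06 for cholesterol biosynthesis, 0.20 for immediate early and 0.12 for mitochondrially encoded genes, none past the threshold.

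Between EAE+BMT+PLX and EAE+BMT the question was what differed with the inhibitor after the transplant. Nlrc4 stood at 1.29 (SE 0.27), Pmepa1 at 1.19 (SE 0.21), Galnt3 at 0.89 (SE 0.18), Anapc15 at -0.93 (SE 0.14), Ppm1l at -0.92 (SE 0.14) and Kitl, the ligand of Kit, at -1.06 (SE 0.20) in myeloid-like nuclei. These are values of the whole class, whose clusters differed in share as given above, and in macrophage-like nuclei taken alone Nlrc4 stood at 0.09 (SE 0.22). By edgeR 0 of 14919 genes passed, 598 had an unadjusted p under 0.05, and DESeq2 called 22. Interferon response genes were higher in 1 of 19, with a median of -0.68 (camera adjusted p = 2.6e-05, and adjusted p = 0.88 with an estimated correlation), -0.72 within D2, 0.11 within D3 and 0.09 without EAE+BMT replicate 1. MHC class I genes stood at -0.35 (adjusted p = 0.030, and adjusted p = 0.94 with an estimated correlation), -0.53 within D2, 0.35 within D3 and 0.54 without EAE+BMT replicate 1. Disease-associated and phagocytic genes had a median of 0.32 (adjusted p = 2.6e-05; Ctsd 0.54, SE 0.21, and Spp1 1.13, SE 0.51; 0.53 and 0.05 within D2 and D3), bone marrow-derived macrophage genes 0.31 (adjusted p = 0.0021; Clec12a 1.13, SE 0.37; 0.17 and 0.21) and proliferation 0.73 (adjusted p = 4.0e-05; Top2a 1.74, SE 0.55; 1.03 and -0.07), and each of the 3 had adjusted p = 0.60 with an estimated correlation. Medians were -0.12 for homeostatic microglia (0.72 and -0.33 within D2 and D3; the median turned to 0.07 without EAE+BMT replicate 2 and to 0.11 with the prefix as a factor), -0.12 for MHC class II, -0.12 for cytokines and chemokines, 0.15 for cholesterol and lipid handling, -0.05 for complement and Fc receptors, -0.07 for cholesterol biosynthesis, 0.00 for p53 targets, 0.01 for immediate early and -0.01 for mitochondrially encoded genes, none past the threshold. For the last 3 of these the median, mean and test direction differed in sign, with means of 0.02, -0.04 and 0.0011.

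In astrocyte-like nuclei of EAE against control, 113 genes rose and 53 fell of 16071. Genes of cholesterol synthesis were lower together: of 17, 0 rose and 9 fell (0 and 16 adjusted over the list alone), with a median of -1.56. Fdps, which makes farnesyl diphosphate, changed by -2.35 (SE 0.33; adjusted p = 0.0080), Nsdhl, a sterol dehydrogenase gene, by -2.12 (SE 0.26; adjusted p = 0.0035), from 90.6 to 20.9 CPM ± 2.96, Msmo1 by -1.81 (SE 0.29), Fdft1, squalene synthase, by -1.69 (SE 0.26), Cyp51 by -1.58 (SE 0.26), Sqle by -1.51 (SE 0.25) and Hmgcs1 by -1.46 (SE 0.21). Insig1, which responds to sterol levels, changed by -1.62 (SE 0.25), Pcyt2, of phospholipid synthesis, by -1.79 (SE 0.23), and Gli1, a mediator of hedgehog signalling, by -1.67 (SE 0.20). Nox4 (ENSMUSG00000030562; chromosome 7, 87246096 to 87398710, plus strand), an oxidase that makes hydrogen peroxide, rose by 2.89 (SE 0.23; adjusted p = 0.00015), from 10.7 to 79.2 CPM ± 4.70. Dysf, of membrane repair, rose by 2.85 (SE 0.33), Ggta1 by 2.81, Adam12, a metalloprotease gene, by 2.75, Sphkap by 2.45, Adamtsl3 by 2.33, Nalcn, a sodium leak channel gene, by 2.30 and Igfbp7 by 2.06. Of 19 reactive astrocyte genes, 3 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 1.70: Cd109 by 1.93 (SE 0.28), Fkbp5, a co-chaperone gene induced by glucocorticoids, by 1.36 (SE 0.24) and Cd44, the hyaluronan receptor, by 1.11 (SE 0.21). Gfap stood at 0.97 (SE 0.35; adjusted p = 0.20) and Serpina3n at 3.31 (SE 1.22; adjusted p = 0.27).

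Camera gave adjusted p = 1.7e-29 for cholesterol biosynthesis and 1.1e-18 for reactive astrocyte genes, and adjusted p = 0.11 and 0.13 with an estimated correlation. Mitochondrially encoded genes moved with them (median -0.89, 0 rose and 1 fell of 8, 0 and 3 adjusted over the list alone, mt-Nd2 -1.20 with SE 0.26; adjusted p = 2.1e-05, and adjusted p = 0.25 with an estimated correlation). Ptprc, the leukocyte gene CD45, stood at 0.30 CPM in control and 10.7 ± 6.34 in EAE astrocyte-like nuclei, against 948 ± 199 in EAE myeloid-like nuclei. Medians were -0.06 for homeostatic astrocyte genes (Aqp4 0.51), 0.06 for p53 targets, 0.78 for immediate early and 0.00 for proliferation genes, none past the threshold. Within prefix D2 the reactive list differed by 1.83, cholesterol biosynthesis by -1.36 and mitochondrially encoded genes by -0.70, and 22 of 22 genes of the naming rule moved the same way. The count of 166 was 45 without EAE replicate 1, 940 and 901 without EAE+BMT replicates 1 and 2, 76, 74 and 100 without EAE+BMT+PLX replicates 1, 2 and 3, and 968 without EAE+BMT replicate 1 and EAE+BMT+PLX replicate 1. It was 1478 with the prefix as a factor and 402 by DESeq2.

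**Figure D4:**
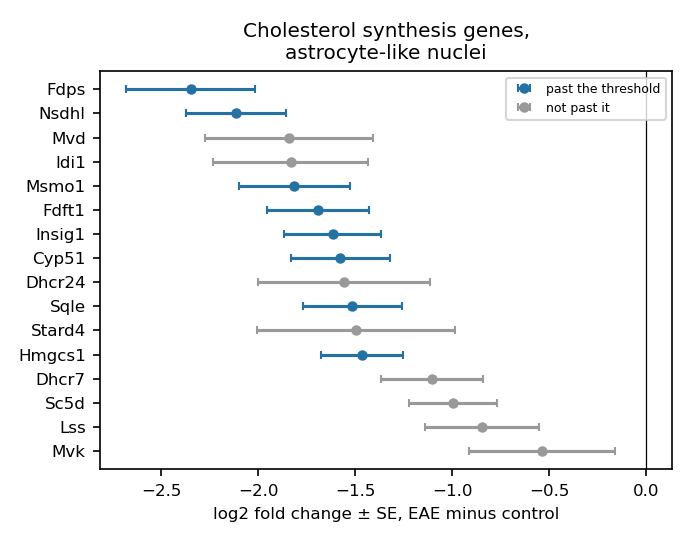
Log2 fold change with SE of 16 of the 17 cholesterol biosynthesis genes in astrocyte-like nuclei, EAE against control; blue points passed the threshold. Fdps stood at -2.35 and Hmgcs1 at -1.46.

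In astrocyte-like nuclei of EAE+BMT against EAE, p53 targets were higher in 13 of 13, with a median of 0.44. Of them 0 passed over all genes by edgeR and 4 rose adjusted over the list alone: Eda2r, a receptor of the TNF receptor family (1.97, SE 0.36), Psrc1 (2.16, SE 0.61), Aen, an exonuclease gene (0.80, SE 0.27), and Ccng1, cyclin G1 (0.77, SE 0.27). Camera gave adjusted p = 1.3e-14, and adjusted p = 0.15 with an estimated correlation, and the difference was 0.73 within D2 and 0.48 within D3. Cholesterol biosynthesis had a median of 0.22 (adjusted p = 0.00070, and adjusted p = 0.60 with an estimated correlation; -0.11 within D2, 0.50 within D3, and a median of -0.11 without EAE+BMT replicate 2). Fkbp5 stood at -1.07 (SE 0.19; adjusted p = 0.60), Nox4 at -0.76 (SE 0.16), Itih5 at -0.71 (SE 0.15), Ephx1 at 0.69 (SE 0.17) and Gli1 at 0.60 (SE 0.17). The median of reactive astrocyte genes was -0.06 (0.27 and -0.54 within D2 and D3; 0.35 without EAE+BMT replicate 2), with Gfap at -0.05 and Serpina3n at 0.29. Medians were 0.07 for homeostatic astrocyte, -0.03 for immediate early, 0.09 for proliferation and -0.11 for mitochondrially encoded genes, none past the threshold. By edgeR 0 of 16071 genes passed, 344 had an unadjusted p under 0.05, and DESeq2 called 2. Counts of 2, 5 and 1 came from fits without EAE replicate 1, EAE+BMT replicate 2 and EAE+BMT+PLX replicate 1.

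In EAE+BMT+PLX against EAE, 1 gene rose and 14 fell in astrocyte-like nuclei. Fkbp5 (ENSMUSG00000024222; chromosome 17, 28399094 to 28517527, minus strand) fell from 302 ± 57.1 to 73.3 CPM ± 13.4, a log2 fold change of -2.04 (SE 0.17; adjusted p = 0.00043). Ccdc3 (ENSMUSG00000026676; chromosome 2, 5137776 to 5230878, plus strand), a secreted protein gene, changed by -1.70 (SE 0.18; adjusted p = 0.0029), Nox4 by -1.22 (SE 0.15), Itih5 by -1.20 (SE 0.14), Galnt18, a glycosyltransferase gene, by -1.15 (SE 0.16), Prune2 by -1.05 (SE 0.14), Lrrc8c, a subunit of volume-regulated anion channels, by -0.95 (SE 0.16) and Slc24a4 by -0.92 (SE 0.12). Nat8f3 rose by 0.92 (SE 0.13). The 9 named genes moved the same way within both prefixes. Of the reactive astrocyte genes 0 rose and 1 fell (0 and 2 adjusted over the list alone), with a median of -0.45, Cd109 at -1.05 (SE 0.19; adjusted p = 0.057) and Gfap at -0.45 (SE 0.25; adjusted p = 0.84). The p53 targets were again higher in 13 of 13 (median 0.59), with 0 past the threshold over all genes by edgeR and 5 adjusted over the list alone, led by Psrc1 (2.28, SE 0.59), Eda2r (1.90, SE 0.35; adjusted p = 0.060) and Sesn2 (1.27, SE 0.35). Homeostatic astrocyte genes had a median of 0.20 and cholesterol biosynthesis 0.39.

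Camera gave these 4 lists adjusted p = 7.5e-10 (reactive), 8.9e-12 (p53 targets), 0.00050 (homeostatic) and 3.1e-06 (cholesterol biosynthesis), and adjusted p = 0.23, 0.20, 0.20 and 0.28 with an estimated correlation. Within D2 and D3 they differed by -0.12 and -0.59, 0.68 and 0.31, 0.31 and 0.04, and 0.42 and 0.26. Medians were 0.05 for immediate early genes (mean -0.06, test direction down), 0.29 for proliferation and 0.15 for mitochondrially encoded genes, none past the threshold. The count of 15 was 7 and 28 without EAE replicates 1 and 2, 75 and 74 without EAE+BMT replicates 1 and 2, and 5, 1 and 4 without EAE+BMT+PLX replicates 1, 2 and 3. It was 51 with the prefix as a factor, 72 in a fit of the compared groups and 63 by DESeq2. Between EAE+BMT+PLX and EAE+BMT, Fkbp5 stood at -0.97 (SE 0.17; adjusted p = 0.69) and Cd109 at -0.88 (SE 0.19; adjusted p = 0.69). There the medians were -0.37 for reactive (adjusted p = 5.2e-08; -0.39 and -0.05 within D2 and D3; 0.15 without EAE+BMT replicate 1), 0.08 for homeostatic (adjusted p = 0.031; 0.16 and 0.05), 0.17 for cholesterol biosynthesis (adjusted p = 0.037; 0.54 and -0.24; -0.06 without EAE+BMT replicate 1) and 0.29 for mitochondrially encoded genes (adjusted p = 0.019; 0.48 and 0.11; -0.01 without EAE+BMT+PLX replicate 2), and with an estimated correlation they had adjusted p = 0.52, 0.52, 0.77 and 0.74. Medians were 0.07 for p53 targets, 0.09 for immediate early genes (mean -0.0030) and 0.18 for proliferation. By edgeR 0 genes passed there, 577 had an unadjusted p under 0.05, DESeq2 called 2, and 43 passed without EAE+BMT replicate 2.

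**Figure D5:**
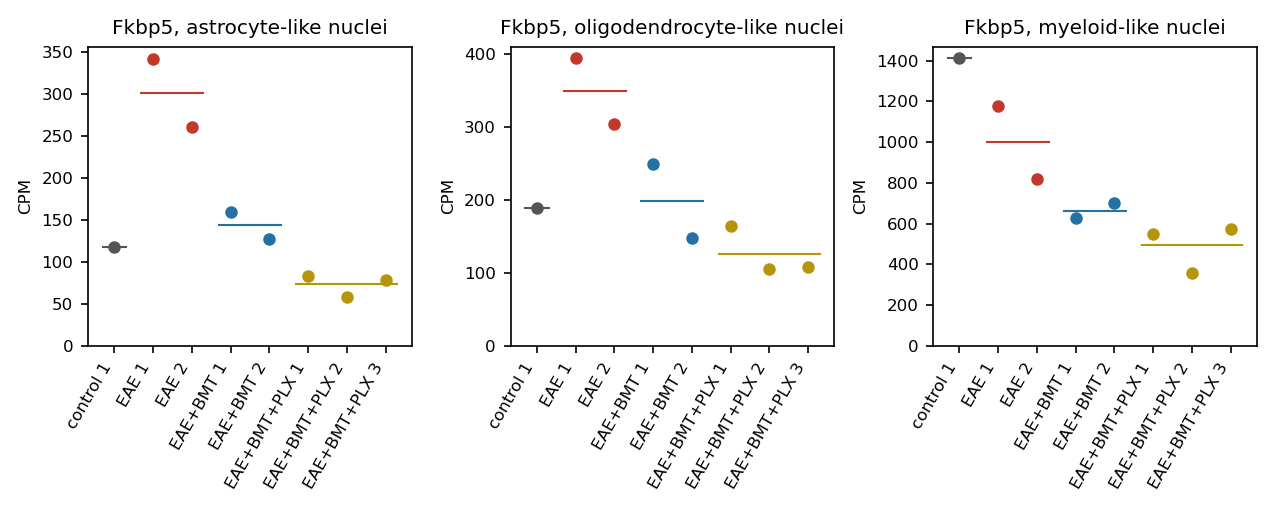
CPM of Fkbp5 per library in astrocyte-, oligodendrocyte- and myeloid-like nuclei, with lines at group means. In astrocyte-like nuclei the means were 302 CPM in EAE and 73.3 CPM in EAE+BMT+PLX.

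In oligodendrocyte-like nuclei of EAE against control, 41 genes rose and 4 fell of 17843. The class lay in different clusters in the 2 groups: 1 cluster held 39.2% of its control and 5.03% of its EAE nuclei, and others 0.25% and 16.5%, and 6.76% and 19.2%. Myof (chromosome 19, 37899036 to 38043577, minus strand), a ferlin of membrane repair, rose by 2.72 (SE 0.37; adjusted p = 0.029), from 5.19 to 34.1 CPM ± 0.44. Pros1 (chromosome 16, 62854307 to 62929346, plus strand), which encodes protein S, a ligand of Mertk, rose by 2.57 (SE 0.28; adjusted p = 0.013). Eya4 rose by 2.19 (SE 0.23), Arhgap15 by 1.98, Sema3e, a semaphorin gene, by 1.91, Lhfpl3, also on the OPC marker list, by 1.86, Cadps2 by 1.67 and Unc13b, of vesicle priming, by 1.52. Cdh10, a cadherin gene, changed by -1.03 (SE 0.17; adjusted p = 0.050); the others that fell, Gm29773 (-2.11, SE 0.35), Ciart (-1.83, SE 0.28) and Gcnt7 (-1.50, SE 0.24), were chosen after their values were seen. Of 18 disease-associated oligodendrocyte genes, 1 rose and 0 fell (5 and 1 adjusted over the list alone), with a median of 1.83: Steap3, an iron reductase gene, was 242 times higher (counting interval 43.2 to 9575), and Serpina3n and C4b stood at 4.64 (SE 0.95; adjusted p = 0.10) and 4.04 (SE 0.55; adjusted p = 0.055). Of 17 cholesterol biosynthesis genes 0 passed by edgeR (0 and 13 adjusted over the list alone rose and fell), with a median of -0.94 and Fdps at -1.59 (adjusted p = 0.067). Mitochondrially encoded genes moved with them, with a median of -1.46 and 0 of 8 past the threshold by edgeR (0 rose and 8 fell adjusted over the list alone; mt-Nd2 -2.01, adjusted p = 0.065). Leukocyte genes moved too: Ptprc rose by 4.33 (SE 0.64; adjusted p = 0.043), from 0.61 to 12.2 CPM ± 0.52, and Dock2 by 3.59 (SE 0.43; adjusted p = 0.013), against 948 and 1576 CPM in EAE myeloid-like nuclei. Arhgap15 was 45.8 times, Myof 7.64 times and Pros1 7.40 times higher in EAE myeloid-like than oligodendrocyte-like nuclei. Ptprc and Dock2 were chosen after their values were seen.

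Camera gave adjusted p = 3.3e-10 for disease-associated oligodendrocyte, 1.4e-13 for cholesterol biosynthesis and 4.0e-10 for mitochondrially encoded genes, and adjusted p = 0.18 for each with an estimated correlation. Within prefix D2 these differed by 1.54, -0.87 and -1.35, and 10 of 10 named genes moved the same way. Medians were -0.20 for myelin genes (Mbp -0.13, SE 0.19), 0.04 for differentiation (-0.03 with bounds), 0.15 for p53 targets, 0.34 for immediate early and -0.05 for proliferation genes, none past the threshold. Of the Y-linked genes only Ddx3y passed the filter, at -2.35 (SE 0.77; adjusted p = 0.15) here and 0.73, 0.45 and -0.28 in the other contrasts. The count of 45 was 17 and 20 without EAE replicates 1 and 2, 1195 and 1225 without EAE+BMT replicates 1 and 2, and 16, 165 and 0 without EAE+BMT+PLX replicates 1, 2 and 3. It was 0 by edgeR with the prefix as a factor, 11 at doubled resolution and 1148 by DESeq2, and 3389 genes had an unadjusted p under 0.05.

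In EAE+BMT+PLX against EAE, 0 genes rose and 4 fell in oligodendrocyte-like nuclei by edgeR, with 992 at an unadjusted p under 0.05 and 109 called by DESeq2. Scrg1 (chromosome 8, 57455923 to 57477585, plus strand) fell from 38.8 ± 9.75 to 12.6 CPM ± 1.51, a log2 fold change of -1.62 (SE 0.18; adjusted p = 0.029). Sgk3 (chromosome 1, 9798107 to 9900845, plus strand), a kinase gene of the SGK family, fell from 636 ± 90.3 to 230 CPM ± 44.4, a log2 fold change of -1.47 (SE 0.16; adjusted p = 0.029). The others, Mrgpra9 (-1.84, SE 0.21) and Gm22146 (-1.60, SE 0.20), were chosen after their values were seen. Myelin genes were higher in 15 of 16, with a median of 0.35, Opalin at 0.50 (SE 0.11; adjusted p = 0.33) and Mbp at 0.08, 0 past the threshold over all genes by edgeR and 1 rising adjusted over the list alone (camera adjusted p = 4.6e-09, and adjusted p = 0.27 with an estimated correlation; 0.51 and 0.13 within D2 and D3). Cholesterol biosynthesis genes were higher in 17 of 17, with a median of 0.36 (adjusted p = 6.9e-07, and adjusted p = 0.52 with an estimated correlation; 0.48 and 0.19). Medians were -0.16 for disease-associated oligodendrocyte genes (0.03 and -0.33 within D2 and D3), -0.07 for differentiation, 0.07 for p53 targets (mean -0.11), 0.00 for immediate early (mean -0.22), -0.05 for proliferation (mean 0.04) and 0.08 for mitochondrially encoded genes (-0.34 without EAE+BMT+PLX replicate 2). The count of 4 was 0 without EAE replicate 1 or any EAE+BMT+PLX replicate, with the prefix as a factor and at doubled resolution. It was 1 without EAE replicate 2, and 71 and 69 without EAE+BMT replicates 1 and 2.

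In EAE+BMT against EAE, cholesterol biosynthesis genes were higher in 16 of 17 in oligodendrocyte-like nuclei (median 0.26; camera adjusted p = 9.3e-07, and adjusted p = 0.91 with an estimated correlation; 0.07 and 0.39 within D2 and D3). Medians were 0.09 for disease-associated oligodendrocyte genes (mean 0.10, test direction down; 0.52 and -0.61 within D2 and D3; 0.57 without EAE+BMT replicate 2), 0.08 for myelin, 0.01 for differentiation, 0.04 for p53 targets, -0.08 for immediate early (mean 0.06), -0.14 for proliferation and -0.02 for mitochondrially encoded genes (mean 0.01), none past the threshold. By edgeR 0 genes passed, 298 had an unadjusted p under 0.05, DESeq2 called 2, and 3 passed without EAE+BMT replicate 2. Between EAE+BMT+PLX and EAE+BMT, myelin genes had a median of 0.24 (adjusted p = 9.3e-08, and adjusted p = 0.35 with an estimated correlation; 0.45 and 0.06 within D2 and D3), with Opalin at 0.48 (SE 0.11). The other medians there were -0.28 for disease-associated oligodendrocyte genes (-0.49 and 0.28 within D2 and D3; 0.34 without EAE+BMT replicate 1), -0.05 for differentiation, 0.08 for cholesterol biosynthesis, 0.02 for p53 targets (mean -0.18), -0.24 for immediate early, 0.12 for proliferation and 0.04 for mitochondrially encoded genes (-0.41 without EAE+BMT+PLX replicate 2). By edgeR 0 genes passed there, 430 had an unadjusted p under 0.05, DESeq2 called 12, and 92 passed without EAE+BMT replicate 2.

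Cell shares and gene lists were tested against the clinical score over the 7 EAE libraries (8 relations, exact two-sided permutation tests across groups). The myeloid-like share had r = 0.73 (exact p = 0.069, adjusted p = 0.25) and rho = 0.84 (exact p = 0.030, adjusted p = 0.12). Group and score were mixed, since EAE libraries (3.5 and 3) had the highest shares. Without the 2 libraries farthest from the median score, both at 1.25, r was 0.36 over a narrower range. The oligodendrocyte-like share had r = -0.74 (exact p = 0.064) and rho = -0.85 (exact p = 0.022, adjusted p = 0.12), and r = -0.45 without those libraries. The T cell-like share had r = 0.68 (exact p = 0.10) and rho = 0.67 (exact p = 0.11). Reactive astrocyte genes had r = 0.52 (exact p = 0.22) and rho = 0.56 (exact p = 0.20), and r = 0.94 (exact p = 0.033) without the 2 libraries. For disease-associated oligodendrocyte genes r was 0.64 and rho 0.60 (exact p = 0.12 and 0.17), for disease-associated and phagocytic genes -0.58 and -0.60 (exact p = 0.17 for both), for homeostatic microglia genes -0.14 and -0.49 (exact p = 0.81 and 0.27) and for MHC class II genes 0.17 and 0.29 (exact p = 0.70 and 0.53). Without the 2 libraries r was 0.79, -0.71, 0.66 and 0.76 for these 4 lists, and 0.85 for T cell-like nuclei. D2 and D3 held 3 EAE libraries each, too few for a test. There r was 0.92 and 0.70 for the myeloid-like share, 0.91 and 0.79 for the T cell-like share, -0.94 and -0.45 for the oligodendrocyte-like share and 0.74 and 0.55 for reactive astrocyte genes. For the disease-associated oligodendrocyte, disease-associated and phagocytic, homeostatic and MHC class II lists it was 0.46 and 0.90, -0.997 and 0.74, -0.64 and -0.48, and -0.47 and 0.79. No relation passed, the smallest adjusted p for r being 0.25.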

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

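Apart from the RNA tests of the p53 targets and of Fkbp5, the tests in this part were chosen only after the result was seen. A GFP sequence stands in each matrix, and the report makes no use of it. In the 5 transplanted libraries a GFP UMI was seen in 7.50% of macrophage-like nuclei (191 of 2548; exact 95% interval 6.50% to 8.59%), 11.3% of B cell-like nuclei (17 of 150), 2.56% of T cell-like nuclei (14 of 546), 0.41% of microglia-like nuclei (5 of 1217; interval 0.13% to 0.96%) and 0.17% of oligodendrocyte-like nuclei (48 of 28293). It was also seen in 1.72% of ependymal-like (6 of 348), 0.87% of endothelial-like (3 of 346), 0.86% of neuron-like (20 of 2321) and 0.66% of fibroblast-like nuclei (4 of 609), a source not tested here. In the 3 libraries without transplant it was seen in 0 of 26410 barcodes, which allows up to 0.0114%. In EAE+BMT replicates 1 and 2 52 of 333 and 3 of 192 macrophage-like nuclei held it, and in EAE+BMT+PLX replicates 1, 2 and 3 it was held by 58 of 1087, 45 of 409 and 33 of 527.

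Free GFP RNA in the droplets would give every class a like rate, but the rate in macrophage-like nuclei was at least 21.2 times that in oligodendrocyte-like nuclei in each of the 5 transplanted libraries, and 58.8 times when pooled. Pooled over libraries, the interval of macrophage-like nuclei also lay above that of ependymal-like (0.64% to 3.71%), endothelial-like (0.18% to 2.51%) and neuron-like nuclei (0.53% to 1.33%). In EAE+BMT replicate 2 alone, macrophage-like nuclei stood at 1.56% (interval 0.32% to 4.50%) and neuron-like nuclei at 0.71% (2 of 283; interval 0.0857% to 2.53%), and these intervals overlapped. Reads of a mouse transcript assigned to GFP would also appear without a transplant; there 0 of 191 macrophage-like nuclei held GFP, which allows 1.57%, under the interval of each transplanted library (lowest bound 4.08%) but EAE+BMT replicate 2. The 192 macrophage-like nuclei there (bound 0.32%) do not decide it alone, but 15 of that library's 10215 barcodes held GFP (0.15%; interval 0.0822% to 0.24%), over the 0.0114% allowed without transplant. Both tests replaced other versions after their values were seen. For replicate 2 that was the bound of 0.32%. In the first version for all libraries the limit without transplant was 0.0201 CPM against 1.51 CPM in the transplanted libraries, or 1.33%, and the bound set for it had been 1%. The signal may come from the transplanted marrow, a hypothesis found and tested on the same data. Whether the donor carried GFP is not given in the sources used here, so this stays open.

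The p53 target genes were higher in astrocyte-like nuclei of each transplanted library than in every library without transplant (5 of 5; mean log2 CPM difference 0.69, exact permutation p = 0.018, the smallest that 56 splits can give; adjusted p = 0.054). Those splits ignore the prefix; over the 18 that keep the transplanted libraries per prefix, exact permutation p = 0.056, the smallest these can give. A batch that follows the file-name prefix is argued against by the difference within prefixes, which was 0.31 at its smallest, above the range of 0.19 between the libraries without transplant. RNA from macrophage-like nuclei would supply at most 2.83% of the CPM that the list gained. The difference was 0.47 (exact permutation p = 0.018; adjusted p = 0.054) in myeloid-like, 0.19 (exact permutation p = 0.036; adjusted p = 0.071) in OPC-like, 0.47 (exact permutation p = 0.057; adjusted p = 0.086) in microglia-like, 0.02 (exact permutation p = 0.88) in oligodendrocyte-like and 0.03 (exact permutation p = 0.81) in macrophage-like nuclei. A candidate explanation is a response to the transplant or its conditioning, which the labels do not describe and which was not tested.

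Fkbp5 stood lower in astrocyte-like nuclei of EAE+BMT+PLX (83.8, 58.2 and 77.9 CPM) than of EAE (342 and 261 CPM), with 159 and 128 CPM in EAE+BMT and 118 CPM in the control. RNA from myeloid-like nuclei would supply at most 14.8% of the CPM that Fkbp5 lost, and a batch that follows the prefix is argued against by log2 ratios of -2.56 and -1.75 (-1.745 before rounding) within D2 and D3. Disease severity stays open: over 7 libraries Fkbp5 had r = 0.69 with the clinical score (exact permutation p = 0.097; rho 0.75, exact permutation p = 0.067), and the EAE+BMT+PLX libraries lay below EAE+BMT replicate 2, of lower or equal score, by log2 ratios of -0.61, -1.14 and -0.72, but a single comparator excludes nothing. EAE+BMT replicate 1 had the score (3.5) and prefix (D2) of EAE replicate 1 and stood at 159 against 342 CPM, again a single pair. In other classes the EAE+BMT+PLX difference from EAE was -1.47 (SE 0.27; edgeR adjusted p = 0.29) in oligodendrocyte-like, -1.02 (SE 0.23; adjusted p = 0.20) in myeloid-like and -0.85 (SE 0.21; adjusted p = 0.34) in OPC-like nuclei. A response to the transplant and the inhibitor may account for it, as a hypothesis. The EAE+BMT+PLX libraries all had lower scores than the EAE libraries, so the score stays open for them.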

How the results depend on the processing

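The 4 alternatives listed last under how the data were processed were chosen only after seeing the data. The rule that a turned direction counts only where either test passed was also set after the values were seen. Of the 86 named results past the threshold, none turned direction under any alternative run, but calls were lost: 38, 36 and 41 without EAE replicate 1, EAE replicate 2 and EAE+BMT+PLX replicate 3, 26 and 13 without EAE+BMT+PLX replicates 2 and 1, 2 and 3 without EAE+BMT replicates 1 and 2, 16 with the replicate block, 15 with the prefix, 8 at doubled resolution, 7 without the filter, 6 with doublets kept, 5 of 43 without the cluster with oligodendrocyte RNA, 4 of 20 with the compared groups alone, 2 with 1000 genes, and 1 each with RLE, every barcode and DESeq2. The minimum of 50 nuclei removed no library, so it tested nothing. The single control could not be left out of its own contrast.

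Counts of genes past the threshold are in the order EAE against control, EAE+BMT against EAE, EAE+BMT+PLX against EAE, and EAE+BMT+PLX against EAE+BMT, and the reported counts by edgeR were 795, 0, 15 and 0 in myeloid-like, 166, 0, 15 and 0 in astrocyte-like and 45, 0, 4 and 0 in oligodendrocyte-like nuclei. DESeq2 gave 1091, 12, 211 and 22, then 402, 2, 63 and 2, then 1148, 2, 109 and 12. No low-count filter gave 1560, 7, 298 and 24, then 1303, 19, 216 and 50, then 843, 1, 52 and 3. The replicate block gave 802, 0, 14 and 0, then 1360, 1, 51 and 5, then 1522, 0, 13 and 0. The file-name prefix as a factor gave 1342, 0, 71 and 0, then 1478, 2, 51 and 1, then 0 in each. The compared groups alone gave 0, 19 and 0, then 0, 72 and 0, then 0, 66 and 0 in the last 3 contrasts. Without EAE+BMT replicate 1 and EAE+BMT+PLX replicate 1 the counts were 1824, 1, 147 and 0, then 968, 1, 41 and 0, then 1504, 11, 74 and 7. Doubled resolution gave 11, 0, 0 and 0 in oligodendrocyte-like nuclei. Leaving out each library gave 362 to 1119, 0 to 3, 0 to 50 and 0 in myeloid-like, 45 to 940, 0 to 5, 1 to 75 and 0 to 43 in astrocyte-like, and 0 to 1225, 0 to 3, 0 to 71 and 0 to 92 in oligodendrocyte-like nuclei. The causes were not tested.

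Correlations cannot tell replicate number from prefix. With group means removed, the libraries of a group of 2 mirror each other. Pairs sharing only a number stood at -0.11 to 0.11 in myeloid-like and -0.20 to 0.01 in astrocyte-like nuclei, partly mirrored prefix values. Pairs sharing a prefix stood at 0.01 to 0.35, 0.17 to 0.59 and, in oligodendrocyte-like nuclei, -0.03 to 0.63, the highest sharing both. With the replicate block the T cell-like rise in EAE was 7.32 (adjusted p = 0.070). Macrophage-like differences with the block were 2.69, 2.03 and 3.59 for contrasts against control or EAE, ordered as above, none passing. Clustering with the marker genes gave 1.77 (adjusted p = 0.13) in the first. Over left-out libraries these ranged from 2.30 to 2.69, from 1.89 to 2.27, and from 3.14 to 3.73, and in EAE+BMT+PLX against EAE+BMT from 1.07 to 1.64. With the prefix as a factor the last was 1.07 (adjusted p = 0.016), and the microglia-like differences were -1.42 (adjusted p = 0.0056) in EAE against control and -0.64 (adjusted p = 0.043) in EAE+BMT+PLX against EAE. Over left-out libraries these last ranged from -1.60 to -1.19 and from -1.80 to -0.66.

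Of 116 list tests 42 passed with the preset correlation and 0 with an estimated one, in each class and contrast. Of 1131 alternative list tests, 923 kept direction and side, 57 gained and 36 lost the call, 98 turned with neither test past the threshold, 10 turned with the alternative past it, and 7 turned with the reported test alone past it. The replicate block gave 3 lists in myeloid-like nuclei of EAE+BMT+PLX against EAE+BMT. Over left-out libraries the lists past the threshold numbered 2 to 9, 2 to 6 and 4 to 11 in myeloid-like nuclei for EAE+BMT against EAE, EAE+BMT+PLX against EAE and EAE+BMT+PLX against EAE+BMT. They numbered 2 to 5 and 1 to 5 in astrocyte-like nuclei for EAE+BMT against EAE and EAE+BMT+PLX against EAE+BMT, and 1 to 2, 2 to 5 and 1 to 4 in oligodendrocyte-like nuclei for the 3 contrasts. Over left-out libraries, the medians for EAE+BMT against EAE ran from -0.61 to -0.051 for homeostatic microglia (test direction turned at the latter), -0.51 to 0.94 for MHC class I, -0.044 to 1.45 for interferon response, -0.14 to 0.60 for cytokines, -0.69 to 0.35 for reactive astrocyte, -0.11 to 0.52 for astrocyte cholesterol biosynthesis and -0.65 to 0.57 for disease-associated oligodendrocyte genes. The medians for EAE+BMT+PLX against EAE+BMT ran from -0.37 to 0.11 for homeostatic microglia, -0.86 to 0.54 for MHC class I, -1.33 to 0.093 for interferon response, -0.90 to 0.15 for reactive astrocyte, -0.060 to 0.46 for astrocyte cholesterol biosynthesis, -0.77 to 0.34 for disease-associated oligodendrocyte, and -0.0079 to 0.55 and -0.41 to 0.23 for mitochondrially encoded genes in astrocyte-like and oligodendrocyte-like nuclei. For EAE+BMT+PLX against EAE the last list ran from -0.34 to 0.25 in oligodendrocyte-like nuclei. The turns with a test past the threshold came without EAE+BMT replicate 1, EAE+BMT replicate 2 or EAE+BMT+PLX replicate 2. The homeostatic microglia median in EAE+BMT+PLX against EAE+BMT was 0.11 with the prefix as a factor. The causes were not tested.

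Without thinning, the share of myeloid-like nuclei with a UMI was 37.4% for Ms4a7 in EAE+BMT, and 49.1%, 39.2% and 30.0% for Sall1 in control, EAE and EAE+BMT. Reactive astrocyte genes had r = 0.94 with the score without the 2 libraries at 1.25 (unadjusted exact p = 0.033). Depth limits what was seen in the control, where 427 of 639 myeloid-like nuclei were too shallow for the shares.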

Other observations

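The class fits of OPC-like, microglia-like and macrophage-like nuclei in this part, and the clock genes and Zbtb16, were chosen only after the data were seen. In OPC-like nuclei of EAE against control, 26 genes rose and 26 fell by edgeR. Among those that rose were Cldn11, a tight junction gene of myelin, by 1.74 (SE 0.24; adjusted p = 0.0057), and Sorcs2 by 2.07 (SE 0.29; adjusted p = 0.0057). Glis3, a zinc finger transcription factor gene, rose by 2.76 (SE 0.47; adjusted p = 0.013), Il33, an alarmin gene, by 1.51 (SE 0.29; adjusted p = 0.025) and Lpar1, a lysophosphatidic acid receptor gene, by 3.52 (SE 0.49; adjusted p = 0.011). The leukocyte genes Ptprc, Ctss and Inpp5d rose there too, by 4.07, 4.40 and 4.04, and mt-Nd2 changed by -2.19 (SE 0.40). Glis3 changed by -2.77 (SE 0.36; adjusted p = 0.0027) in EAE+BMT against EAE, where 1 gene rose (Pstpip2, 1.25, SE 0.17) and 2 fell (Glis3 and Kcnb2, the latter at -1.17, SE 0.18), and by -3.22 (SE 0.32; adjusted p = 1e-04) in EAE+BMT+PLX against EAE, where 3 rose (Rph3a, Pnlip and Pstpip2) and 13 fell. These genes were chosen after their values were seen. Mertk, a phagocytic receptor gene, changed by -1.02 (SE 0.15; adjusted p = 0.0054) and Matn2, a matrix protein gene, by -1.57 (SE 0.23; adjusted p = 0.0054) in that contrast, and Rph3a rose by 1.54 (SE 0.21; adjusted p = 0.0047). Ptprc went from 10.47 ± 0.93 to 4.21 CPM ± 1.03 there, and Inpp5d from 10.57 ± 3.93 to 2.26 ± 1.24. The part of such leukocyte RNA in these falls was not tested.

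In microglia-like nuclei taken alone (7 libraries), 128 genes rose and 47 fell in EAE against control by edgeR, and 0 passed in EAE+BMT against EAE, with 232 at an unadjusted p under 0.05. In EAE+BMT+PLX, Frmpd4 passed against EAE (1.82, SE 0.20), and Tafa2 (2.17, SE 0.30) and Prkg1 (-1.63, SE 0.23) against EAE+BMT, all 3 chosen after their values were seen. Trps1, a transcription factor gene, rose in EAE against control by 2.55 (SE 0.23; adjusted p = 0.00025), Myo5a, a motor protein gene, by 2.45 (SE 0.28; adjusted p = 0.0024) and Abca1 by 1.73 (SE 0.27; adjusted p = 0.0098), while Prkce, a protein kinase C gene, changed by -1.29 (SE 0.18; adjusted p = 0.0047). St18, on the oligodendrocyte marker list, rose there by 1.88 (SE 0.28; adjusted p = 0.0057). In macrophage-like nuclei 1 gene passed in EAE+BMT+PLX against EAE, Clmp (-3.16, SE 0.34), chosen after its values were seen. Macrophage-like nuclei lay in different clusters in these groups, as given above, a limit on each value of this class. Zbtb16, a glucocorticoid-responsive transcription factor gene, stood at -1.16 (SE 0.27; adjusted p = 0.43) in oligodendrocyte-like and -2.22 (SE 0.47; adjusted p = 0.45) in macrophage-like nuclei in that contrast. Of 4 clock genes looked at, not a list fixed beforehand, Per3 changed by -1.61 (SE 0.29; adjusted p = 0.018) and Arntl rose by 0.95 (SE 0.22; adjusted p = 0.041) in myeloid-like nuclei of EAE against control, where Per2 stood at 0.10 (SE 0.30; adjusted p = 0.92) and Dbp at -1.63 (SE 0.52; adjusted p = 0.10). In astrocyte-like nuclei of EAE+BMT+PLX against EAE, Dbp stood at 0.93 (SE 0.17; adjusted p = 0.057), Per3 at 0.71 (SE 0.13; adjusted p = 0.060), Per2 at 0.56 (SE 0.13; adjusted p = 0.23) and Arntl at -0.51 (SE 0.17; adjusted p = 0.48). An oligodendrocyte-like cluster of 1992 nuclei, whose leading genes against other classes were Ddc, Gm19500 and Sec14l5, drew 1342 of them from EAE+BMT replicate 1. Another myeloid-like cluster of 239 nuclei carried oligodendrocyte RNA.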
